A study of Mus musculus with 81 samples.

How the data were processed

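Open chromatin was measured by bulk ATAC-seq (sequencing of DNA that a transposase can reach) in 81 libraries of 3 mouse lung adenocarcinoma cell lines, 1183T3, 860T3 and 853T2. Per the labels' protocols, the lines were derived from individual tumours that started in alveolar type II cells after recombination of Kras and p53. Knockouts (KO) used lentiviral Cas9 with guides against Runx1, Runx2 or Runx3. The groups labelled OE used CRISPR activation, in which a truncated guide recruits a transcriptional activation complex to the gene. There were 2 kinds of control, a control guide (sgCON) and cells with Cas9 only (Cas9 control). No label says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

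The authors deposited a table of raw read counts per peak and library, with the positions of 285956 peaks of 300 bp each. Per the submitters' processing notes, bcl2fastq, Bowtie2, SAMtools, Picard and MACS2 2.1.2 were used. The builds hg19 and mm10 are listed there without their roles. How the peaks of the libraries were combined is not given in the sources used here. Positions were read as mm10, the mouse build named there. The order of the positions was checked against that of the counts, and the build with it, by the signal near gene ends of an mm10 table. Mean log2 signal near gene ends was 2.33 in the order given, and 1.24 or 1.23 with the positions shifted by 1 peak. Of all peaks, 31 had no read in any library.

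Library totals ran from 200586 to 8490837 counts, and 11 libraries held fewer than 500000. Intervals and floors given for low counts cover counting error only. Before averaging, the 111 pairs of libraries of the same line, perturbation and guide were compared by a chi-square test of their counts, over peaks with at least 20 reads in the pair (at least 10 where fewer than 300 peaks had that many). In 31 pairs the counts differed by less than the sampling noise, at a p above 0.01. Libraries joined by such pairs may be 1 library sequenced several times. They were summed and counted as 1 sample, which left 59 samples from the 81 libraries.

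Peaks were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr, estimateDisp, glmQLFit and glmQLFTest) on the counts as deposited, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each line had 1 fit over all its samples, with the guides against 1 gene pooled as 1 group. Knockouts were set against sgCON and activation against the Cas9 control of the same line. Contrasts between lines, and the difference of an effect between lines, came from fits over the samples concerned. CPM are counts scaled to the TMM-adjusted library totals. Gene values are sums over the peaks whose centre lay in a protein-coding gene or within 5 kb of either of its ends, from a reference table of 21631 protein-coding genes on mm10 that gives no strand. A gene value therefore measures accessibility over the gene and its surroundings, not expression. Neat1 and Malat1, which are not protein-coding, were added as sums over the peaks between their ends. Group means and ranges of Runx1, Runx2, Runx3, Neat1 and Malat1 were scaled with these 2 genes in the table, and those of other genes without them. Distances between peaks and genes used GenomicRanges 1.54.1.

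There were 20 fixed gene lists. They cover alveolar type I and II cells, airway epithelium, gut and liver endoderm, epithelial identity, epithelial to mesenchymal transition (EMT), bone and cartilage matrix, extracellular matrix, RUNX family and partners, AP-1 and immediate early genes, TGF-beta, YAP/TAZ targets, interferon and antigen presentation, NF-kB and cytokines, p53 targets and cell cycle. Lists for hematopoietic, fibroblast, endothelial, and neuronal and neuroendocrine genes stood for other cell types. Lists were tested with camera (limma 3.58.1) at its preset correlation of 0.01, with adjustment over the lists of a comparison, and again with an estimated correlation. Counts of list members were also adjusted over the list alone. Of the list genes, 2 (Mx1 and Mx2) matched no gene of the table.

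The genes named in the text follow a rule. Runx1, Runx2 and Runx3 were always named. From peaks past the threshold with an absolute log2 fold change of at least 1, the same sign for every guide and a centre in or within 5 kb of a protein-coding gene, the rule took the 6 genes with the smallest p in each direction (3 for comparisons of controls, and none between lines). From each fixed list it took up to 3 members with the smallest p past the threshold. The text names a part of these. Neat1, Malat1, the Cdkn2 segment, the Trp53 peak and single peaks of Runx1 were chosen after their values were seen.

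The comparisons, lists, rule and most other settings were fixed before the data were examined. These settings changed the normalization (DESeq2 1.42.0 size factors, library size only, loess offsets), the filter, the test (DESeq2 Wald test), the control, the treatment of guides, the groups in the fit, the replicate number as a block, the threshold, and the samples, by leaving out each in turn. Settings added later merged no replicates or more of them (variance ratio under 1.2, giving 42 samples), or left out samples under 500000 counts. Others left out the 4 samples with under 15% of their counts in the 5000 strongest peaks, corrected for local copy number over windows of 501 peaks, or added a term for the run of columns. The columns of the count table fell into 3 runs of 18, 27 and 36 libraries, which stand for possible preparation batches that the labels do not name. The first run held all Runx1 KO libraries and no other. Motif accessibility was not analysed here.

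The fits were tested on simulated counts drawn from the real means and library totals, with 200 changed peaks. For Runx1 KO in 1183T3 (59753 peaks) 28.6% of 2-fold, 78.3% of 4-fold and 91.1% of 8-fold changes were recovered. At 4-fold, recovery was 61.5% for Runx3 KO in 860T3 (59626 peaks) and 83% for Runx2 OE in 853T2 (37040). It was 2.5% to 39.5% between lines and 22% to 55.8% for differences of effects.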

Results

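Chromatin accessibility was measured by bulk ATAC-seq in 3 mouse lung adenocarcinoma cell lines in which Runx1, Runx2 or Runx3 was targeted with CRISPR guides or Runx2 or Runx3 was activated with CRISPR activation. The deposited table held counts of 81 libraries over 285956 peaks. Knockouts of all 3 genes were made in the lines 1183T3 and 860T3, and activation of Runx2 and Runx3 in the lines 1183T3 and 853T2. Libraries of 1 guide that differed by less than sampling noise were counted as 1 sample, which left 59 samples. In 1183T3 these were 4 Cas9 controls, 3 sgCON controls, 8 Runx1, 7 Runx2 and 2 Runx3 knockout samples, and 3 Runx2 and 5 Runx3 activation samples. In 860T3 they were 1 Cas9 and 2 sgCON controls, with 8 Runx1, 6 Runx2 and 2 Runx3 knockout samples. In 853T2 they were 2 Cas9 controls with 3 samples for each activated gene. Counts in peaks ran from 200586 to 8490837 per library, and 11 libraries held fewer than 500000.

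The 1183T3 sgCON controls differed among themselves in how strongly their reads gathered in the strongest peaks. The 5000 strongest peaks held 22.9, 9.73 and 8.32 percent of the counts of these 3 samples, against 24.4 to 27.6 percent in the Runx1 knockouts and 19.7 to 23 percent in the Runx2 knockouts of this line. The Cas9 controls of 1183T3 stood at 22.5 to 27.2 percent. Of the 2 Cas9 controls of 853T2, 1 stood at 13.7 percent and the other at 23.3 percent. For each comparison that used these controls the number of changed peaks is therefore also given without the samples under 15 percent, which left 1 sgCON sample in 1183T3 and 1 Cas9 sample in 853T2, each assumed to vary like the other groups. The 2 left out of 1183T3 were the only sgCON samples of that line in their run of columns of the count table, and the 1 of 853T2 was the only control in the run that held all activated samples. The Cas9 control replicate 5 of 1183T3 was likewise the only Cas9 sample of that line in this run, so leaving out the low-share controls or this replicate also takes the controls out of a run.

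**Figure D1:**
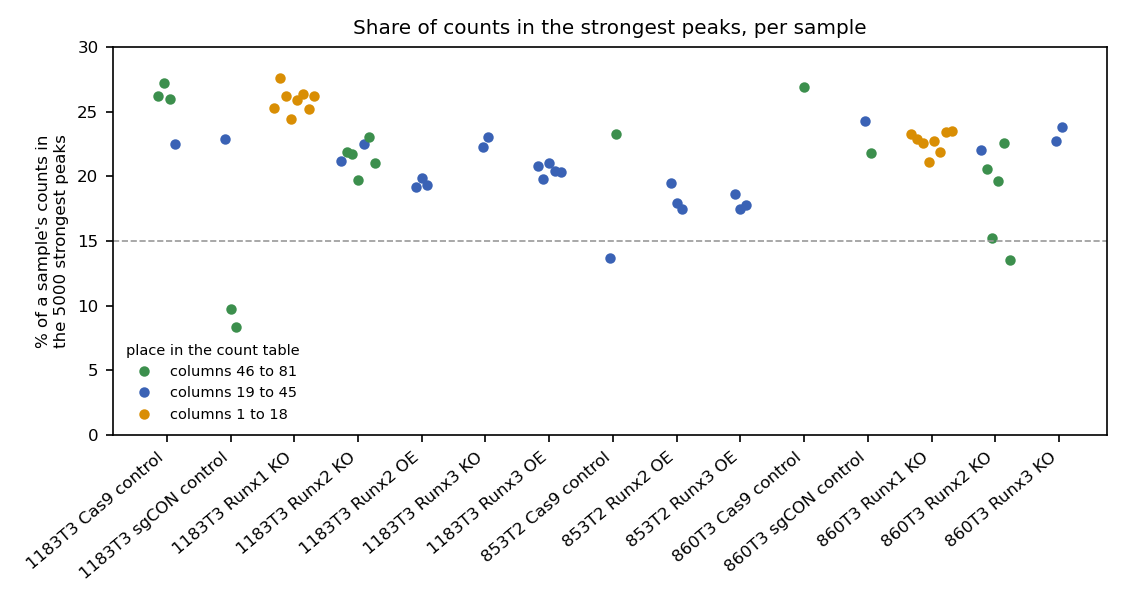
Percent of each sample's counts in the 5000 strongest peaks, 1 point per sample, by line and group, coloured by place in the count table, with a dashed line at 15 percent. In 1183T3, 2 sgCON samples lie below every other sample of that line.

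**Figure D2:**
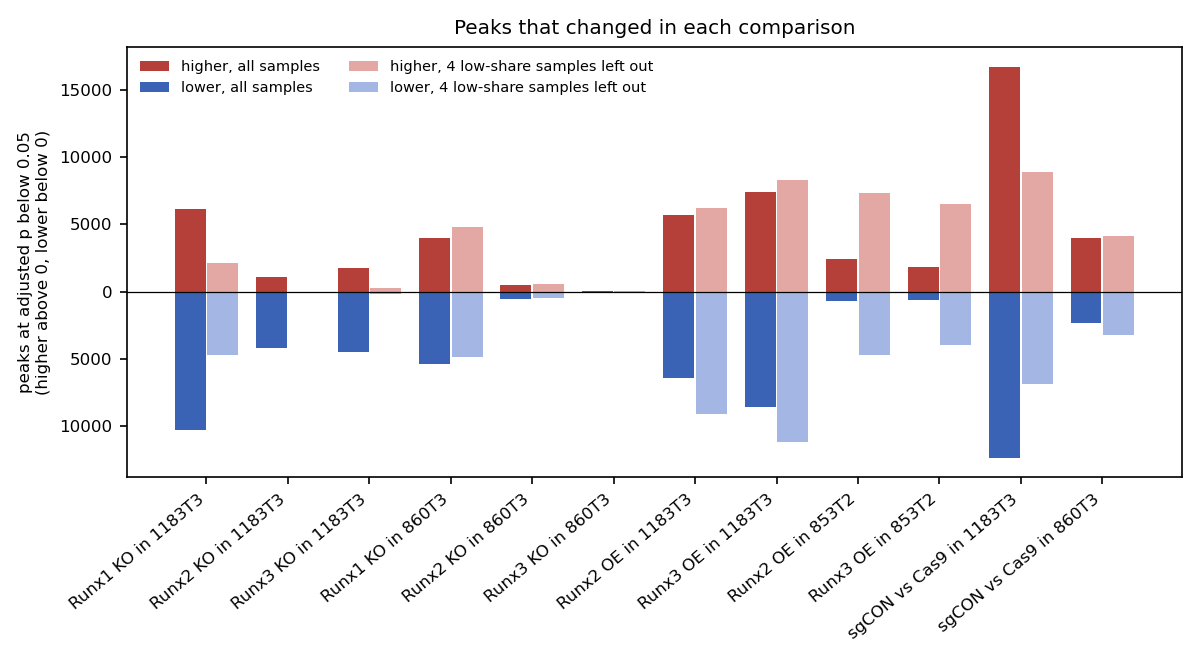
Number of peaks higher (red, above 0) and lower (blue, below 0) at an adjusted p below 0.05 in each comparison, with all samples (dark) and without the 4 low-share samples (light). Without these samples the counts of Runx2 and Runx3 knockouts in 1183T3 shrink and those of activation in 853T2 grow.

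In the Runx1 knockouts of 1183T3 the summed accessibility over Runx1 was 496 ± 42 CPM in 8 samples (414.9 to 549.2), against 491 ± 25.8 in 3 sgCON samples (461.7 to 509.1; adjusted p = 0.993), and with loess scaling it was lower by 0.21 (adjusted p = 0.0272). Summed accessibility over a gene does not check a knockout made by small edits. Within Runx1, 5 peaks rose and 3 fell. A peak inside Runx1 at 16:92778053-92778352 (mm10) held 0 reads in the 8 knockout libraries and 22 in the 5 sgCON libraries, at least 3.88-fold lower (adjusted p = 0.0032). Runx2 rose (log2 fold change 0.52 ± 0.09, adjusted p = 1.8e-05) and Runx3 fell (-1.75 ± 0.42, adjusted p = 0.00117). Without the 2 low-share sgCON samples neither passed, at 0.27 (adjusted p = 0.147) for Runx2 and -0.75 (adjusted p = 0.448) for Runx3.

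Atf3, a stress-induced transcription factor, rose from 168.9 ± 15.09 CPM in 3 sgCON samples to 633.9 ± 112.6 in 8 knockout samples (1.92 ± 0.17, adjusted p = 1.86e-10). Jund rose by 0.92 ± 0.12 (adjusted p = 4e-07), Jun by 0.88 ± 0.12 (adjusted p = 1.71e-06) and the growth-restraining Btg2 by 1.58 ± 0.11 (adjusted p = 9.09e-13). In the AP-1 and immediate early list 12 of 16 genes rose and 0 fell, and 13 rose and 1 fell when adjusted over the list alone. The list passed in camera (adjusted p = 6.47e-07, and adjusted p = 0.00408 with an estimated correlation). Without the 2 low-share sgCON samples it passed with adjusted p = 2.13e-05, and over its 5 alternatives the adjusted p ran from 1.15e-07 to 0.000745. The summed list stood at 3310 to 4005 CPM in the knockouts, 2128 to 2501 in sgCON and 2919 to 3242 in the Cas9 controls, so part of the rise may lie in the sgCON samples. Against the Cas9 controls Atf3 (1.86), Btg2 (1.78) and Jund (0.79) kept their calls and Jun did not pass (0.00).

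Single chemokine, NF-kB and Id genes rose as well. The chemokine genes Cxcl1 (1.63 ± 0.17, adjusted p = 8.03e-09) and Ccl2 (1.91 ± 0.21, adjusted p = 3.68e-08) and the NF-kB inhibitor Nfkbia (0.96 ± 0.14, adjusted p = 3.81e-06) rose. The NF-kB and cytokine list, with 8 genes up and 4 down of 20, did not pass (adjusted p = 0.0605). Id3 rose by 1.32 ± 0.14 (adjusted p = 5.49e-09) and Id1 from 121.1 ± 60.66 to 281 ± 34.92 CPM (adjusted p = 1.75e-07). The keratin gene Krt8 rose by 1.05 ± 0.14 (adjusted p = 9.84e-07) and Twist2, which encodes a mesenchymal transcription factor, by 1.24 ± 0.17 (adjusted p = 1.44e-06). Twist2 did not pass against the Cas9 controls (0.15). The p53 target list passed with 5 of 18 genes up (adjusted p = 0.0249) and was lost at adjusted p = 0.136 with an estimated correlation.

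The alveolar type 2 list fell in the Runx1 knockouts of 1183T3, with 12 of 20 genes down and 0 up, and 13 down and 1 up when adjusted over the list alone (camera adjusted p = 0.0102). It was lost at adjusted p = 0.518 with an estimated correlation. Napsa, an alveolar type 2 protease gene, fell by 1.90 ± 0.25 (adjusted p = 5.9e-07) and Cd74, an antigen-presentation gene, by 2.28 ± 0.39 (adjusted p = 2.98e-05). Lists of other cell types moved the same way. Of 17 hematopoietic genes 10 fell (adjusted p = 0.00592), and of 17 endothelial genes 11 fell and 1 rose (adjusted p = 0.0249), both lost at adjusted p = 0.518 with an estimated correlation. Without the 2 low-share sgCON samples these 3 lists pointed up and did not pass, at adjusted p = 0.586, 0.977 and 0.869, and Napsa (-0.64) and Cd74 (-0.65) did not pass either. Over their 5 alternatives the adjusted p ran from 0.0112 to 0.586 for alveolar type 2, from 0.00194 to 0.977 for hematopoietic and from 0.00194 to 0.869 for endothelial genes.

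The remaining lists did not pass in this comparison. Cell cycle genes, 5 up and 1 down of 22, stood at adjusted p = 0.0788, and interferon and antigen presentation genes, 1 up and 9 down of 22, at 0.233. Gut and liver endoderm genes, 2 up and 7 down of 20, stood at 0.257 and extracellular matrix genes, 1 up and 4 down of 21, at 0.307. Fibroblast genes (2 up and 5 down of 16, adjusted p = 0.382), neuronal and neuroendocrine genes (4 up and 4 down of 14, adjusted p = 0.822), alveolar type 1 genes (3 up and 8 down of 19, adjusted p = 0.622) and bone and cartilage matrix genes (2 up and 5 down of 17, adjusted p = 0.877) did not pass either. The airway list (3 up and 2 down of 14, adjusted p = 0.546) had a median of 0.108 and a mean of -0.275, and the TGF-beta list (3 up and 3 down of 20, adjusted p = 0.622) a median of -0.0723 and a mean of 0.0301. Mesenchymal, epithelial identity, RUNX partner and YAP/TAZ genes stood at adjusted p = 0.872, 0.908, 0.872 and 0.98.

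Of 72907 peaks tested in this comparison 16439 changed, 6133 up and 10306 down. With loess scaling the split turned to 5856 up and 4233 down. A peak inside Tex14 (11:87448758-87449057) rose from 40.66 ± 17.33 to 279.5 ± 50.52 CPM (2.70 ± 0.21, adjusted p = 4.53e-15). A peak inside Dusp16 (6:134802687-134802986) rose by 2.99 ± 0.25 (adjusted p = 2.17e-13) and a peak inside Slc6a6 (6:91729810-91730109) by 2.21 ± 0.21 (adjusted p = 1.45e-11). Peaks inside Mroh4 (15:74622953-74623252; -2.73 ± 0.33, adjusted p = 1.79e-08) and Lpcat3 (6:124689057-124689356; -2.84 ± 0.38, adjusted p = 1.8e-07) fell. These 5 peaks kept their calls without the 2 low-share sgCON samples, where 6838 peaks changed (2134 up, 4704 down). The count was 9228 without the merged sgCON sample of replicates 3, 4 and 5, and 9255 without sgCON replicate 2. The Runx1 knockout libraries of both lines filled a column run of the count table of their own, so preparation and knockout could not be separated.

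In the Runx1 knockouts of 860T3 the summed accessibility over Runx1 rose, from 626 ± 32.8 CPM in 2 sgCON samples (602.8 to 649.2) to 826 ± 58.7 in 8 samples (726.8 to 928.1; 0.40 ± 0.08, adjusted p = 0.00176). With loess scaling it did not pass (0.01). Runx2 (0.17 ± 0.09, adjusted p = 0.261) and Runx3 (0.04 ± 0.14, adjusted p = 0.912) did not pass. Ptgs2, which encodes the inducible cyclooxygenase, rose from 57.3 ± 1.262 to 119.1 ± 18.37 (1.07 ± 0.15, adjusted p = 5.37e-05). The chemokine gene Ccl20 rose by 0.93 ± 0.21 (adjusted p = 0.00444) and Cxcl2 by 0.87 ± 0.25 (adjusted p = 0.024). The NF-kB and cytokine list passed with 5 of 20 genes up and 0 down (adjusted p = 0.00431, and adjusted p = 0.0383 with an estimated correlation). Atf3 (0.77 ± 0.15, adjusted p = 0.00159) and Egr1 (0.39 ± 0.10, adjusted p = 0.0159) rose, while the AP-1 list, with 3 up and 1 down of 16, did not pass (adjusted p = 0.174).

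The YAP/TAZ target list rose with 5 of 19 genes up (adjusted p = 0.0106) and was lost at adjusted p = 0.352 with an estimated correlation. It passed in 3 of 5 alternatives (up to adjusted p = 0.258). In sgCON against Cas9 in 860T3 it pointed down (adjusted p = 0.0529, and 0.0226 to 0.0447 in the 6 alternatives), so part of the rise may lie in the sgCON controls. The connective tissue growth factor gene Ccn2 rose by 1.26 ± 0.18 (adjusted p = 6.69e-05), Crim1 by 0.46 ± 0.11 (adjusted p = 0.00579) and the TEAD gene Tead1 by 0.49 ± 0.11 (adjusted p = 0.00475). The extracellular matrix list, with 3 up and 1 down of 22 (adjusted p = 0.0106), and the endothelial list, with 3 up of 18 (adjusted p = 0.0147), were both lost at adjusted p = 0.352. The RUNX family and partner list, with 4 up of 15 (adjusted p = 0.0112), was lost at adjusted p = 0.0826 with an estimated correlation. Fbln2 (1.06 ± 0.13, adjusted p = 1.15e-05), Timp3 (0.56 ± 0.10, adjusted p = 0.000568), Hipk2 (0.48 ± 0.10, adjusted p = 0.00246) and Twist2 (0.70 ± 0.16, adjusted p = 0.00509) rose. Against the 1 Cas9 sample Atf3, Ccn2, Crim1, Cxcl2, Egr1 and Hipk2 did not pass, and Ccl20 (-0.49) and Ptgs2 (-0.14) changed sign. With loess scaling Egr1, Hipk2 and Tead1 did not pass.

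Of 72690 peaks tested in 860T3 the Runx1 knockout changed 9365, 3959 up and 5406 down, and under loess scaling 5146 went up and 4000 down. A peak 0.758 kb outside Egr1 (18:34865565-34865864) rose from 16.35 ± 4.353 to 77.72 ± 14.13 CPM (2.28 ± 0.21, adjusted p = 3.53e-13), with peaks inside Dgkd (1:87901038-87901337; 2.13 ± 0.21, adjusted p = 5.76e-12) and Tns3 (11:8463255-8463554; 3.33 ± 0.33, adjusted p = 8.24e-12). Peaks beside Ddx54 (5:120612851-120613150; -1.83 ± 0.19, adjusted p = 9.07e-12) and Ntmt1 (2:30807633-30807932; -1.61 ± 0.17, adjusted p = 1.37e-11) fell. The count ran from 7092 to 12926 with single samples left out. It was 17591 against the Cas9 sample, 15747 with every library its own sample, 5620 with the stricter filter and 4127 with counts summed per guide.

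Neat1, a long noncoding RNA gene of nuclear paraspeckles, opened in the Runx1 knockouts of both lines. Its summed accessibility was 9190 ± 3870 CPM in 8 knockout samples of 1183T3 against 339 ± 127 in 3 sgCON samples (4.76 ± 0.32, adjusted p = 1.26e-13). In 860T3 it was 2970 ± 1610 in 8 samples against 378 ± 16.5 in 2 (2.97 ± 0.41, adjusted p = 3.67e-05). The knockouts of Runx2 stood at 381 ± 88.2 and 315 ± 76.6. Of 26 peaks between 19:5824708 and 19:5845480, 25 rose in 1183T3 and 26 in 860T3, with medians of 3.94 and 3.45. Peaks within 10 kb on either side also rose, with medians of 2.03 and 2.11 against -0.168 and -0.0537 over all peaks. The neighbouring Malat1 rose in 1183T3 (1.07 ± 0.16, adjusted p = 2.86e-06) and did not pass in 860T3 (0.16 ± 0.19, adjusted p = 0.654). The lines differed for Malat1 (0.86 ± 0.26, interaction adjusted p = 0.017) and for Neat1 (1.75 ± 0.53, adjusted p = 0.0172).

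**Figure D3:**
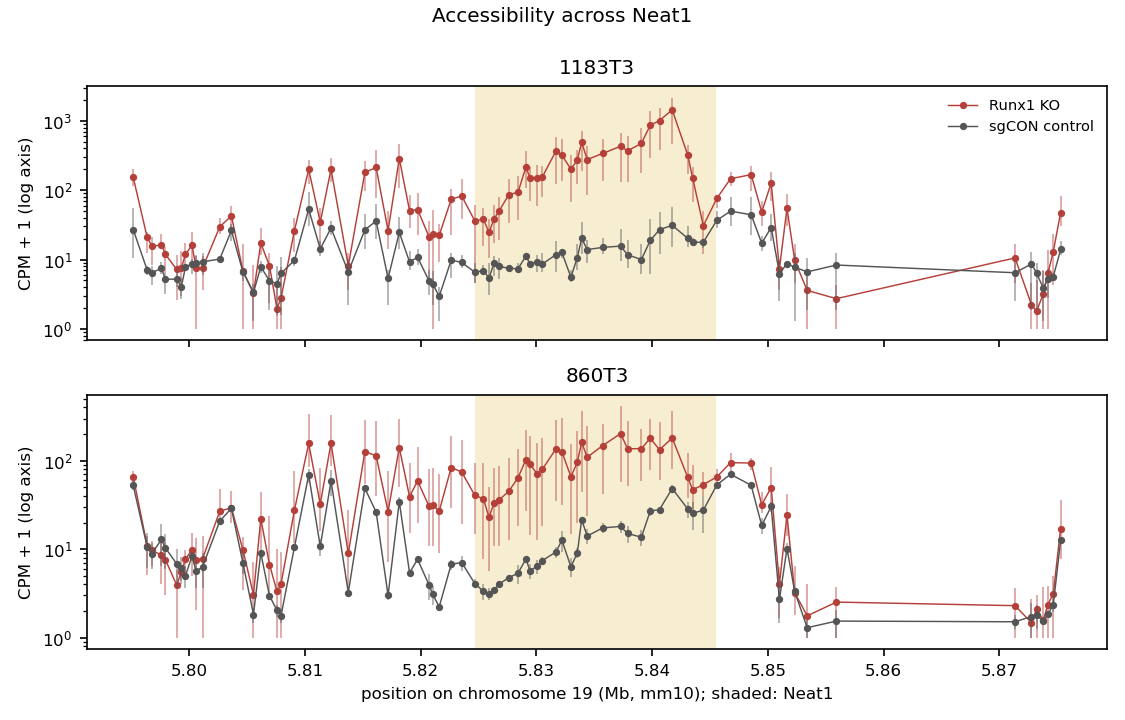
CPM plus 1 on a log axis for each peak around Neat1 (shaded) by position on chromosome 19, in Runx1 knockout (red) and sgCON (grey) samples of 1183T3 and 860T3, with points at the mean and bars over the range of samples. The knockouts lie higher across the gene and over the peaks on its lower side.

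Of 57145 peaks tested in both lines 661 rose in both where 339 were expected from independent lists, 398 fell in both (619) and 872 changed in opposite directions. Over these peaks the Runx1 knockout effects of the 2 lines were unrelated in size (r = -0.0106). The knockout effect differed between lines at 7739 of 46193 peaks, and at 5841 without the low-share samples. The effect was higher in 1183T3 for Atf3 (interaction 1.13 ± 0.18, adjusted p = 0.000132), Jund (adjusted p = 0.000539), Jun (adjusted p = 0.00203), Btg2 (1.29 ± 0.16, adjusted p = 3.58e-06), Ccl2 (adjusted p = 0.000131) and Id3 (adjusted p = 4.06e-05). Ptgs2 (-1.42 ± 0.23, adjusted p = 0.000101), Ccn2 (-1.61 ± 0.27, adjusted p = 0.000144) and Fbln2 (adjusted p = 0.000397) had higher effects in 860T3, the line where they rose. Runx3 (-1.80 ± 0.38, adjusted p = 0.00157), Napsa (-1.80, adjusted p = 0.00745) and Cd74 (-2.94, adjusted p = 0.00092) had lower effects in 1183T3, where without the 2 low-share sgCON samples none of the 3 passed. The differences of Twist2 (0.53, adjusted p = 0.113), Timp3 (-0.38, adjusted p = 0.146) and Runx2 (0.33, adjusted p = 0.0525) did not pass. The AP-1 (adjusted p = 0.000449) and endothelial (0.000566) lists differed most between lines and were lost at 0.158 and 0.323 with an estimated correlation.

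**Figure D4:**
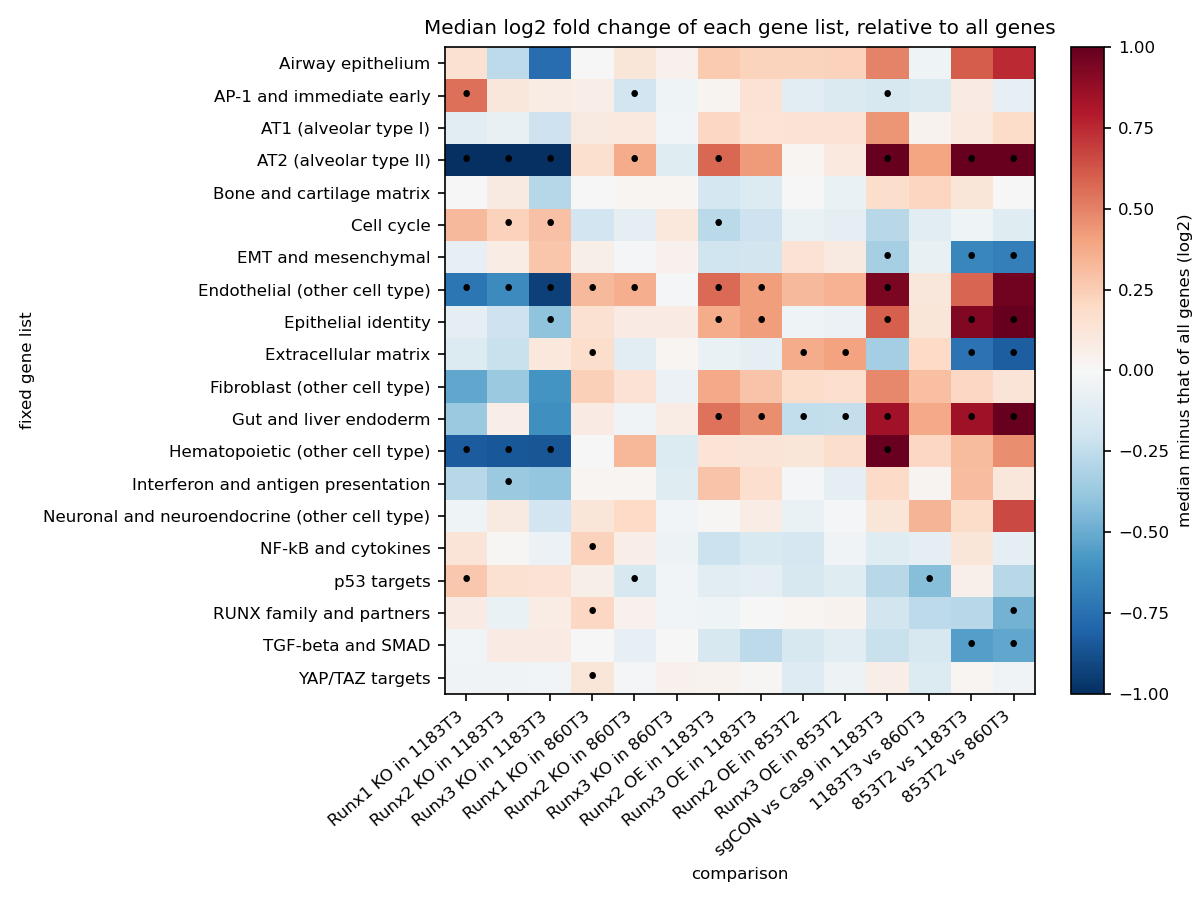
Median log2 fold change of each fixed list minus that of all genes, by comparison, with a dot where the list passed in camera at its preset correlation. Alveolar type 2 genes are lower in the knockouts of 1183T3 and higher in sgCON against Cas9, and AP-1 genes are higher in the Runx1 knockout of 1183T3.

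In the Runx2 knockouts of 1183T3 the summed accessibility over Runx2 was 466 ± 23.7 CPM in 7 samples (445.6 to 507.7) against 382 ± 64.5 in 3 sgCON samples (336.8 to 455.9), a rise of 0.27 ± 0.09 (adjusted p = 0.0182). It was 0.03 without the 2 low-share sgCON samples. Runx3 fell from 37.8 ± 17.1 to 19.4 ± 15 (adjusted p = 0.0286) and Runx1 did not pass (adjusted p = 0.251). Of 20 alveolar type 2 genes 14 fell and 0 rose, 15 when adjusted over the list alone (camera adjusted p = 8e-05). Among them were the surfactant gene Sftpb (-1.65 ± 0.33, adjusted p = 0.000749) and the surfactant lipid gene Lpcat1 (-1.26 ± 0.24, adjusted p = 0.000523). Of 17 hematopoietic genes 10 fell and 1 rose (adjusted p = 0.00295), with Ikzf1 at -2.47 ± 0.48 (adjusted p = 0.000618). Of 17 endothelial genes 7 fell (adjusted p = 0.00349), with Pecam1 at -1.26 ± 0.24 (adjusted p = 0.000553). The cell cycle list, with 1 gene up of 22 (adjusted p = 0.0357), and the interferon list, with 9 down and 1 up of 22 (adjusted p = 0.0439), passed as well. All 5 lists were lost at adjusted p = 0.4 with an estimated correlation. Jun (0.48 ± 0.12, adjusted p = 0.00404), Egr1 (0.56 ± 0.14, adjusted p = 0.0041) and Twist2 (0.72 ± 0.17, adjusted p = 0.00269) rose.

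These calls were lost without the 2 low-share sgCON samples. Of 72907 peaks 5238 changed in the Runx2 knockouts (1053 up, 4185 down), with 292 up and 265 down under loess scaling. The count was 22 without these 2 samples, 0 without the merged sgCON sample of replicates 3, 4 and 5, 34 without sgCON replicate 2 and 16508 without sgCON replicate 1. The peaks inside Foxp1 (6:99012005-99012304; 1.67 ± 0.30, adjusted p = 0.00109) and Slc6a6 (6:91729810-91730109; 1.11 ± 0.21, adjusted p = 0.00165) rose, and the peaks 1.18 kb outside Cdk10 (8:123233287-123233586; -3.81 ± 0.59, adjusted p = 0.000997) and inside Mroh2a (1:88235181-88235480; -4.40 ± 0.70, adjusted p = 0.000997) fell. Without the 2 samples each of these genes and peaks lost its call, and Lpcat1 (0.29), Sftpb (0.35) and Ikzf1 (0.33) changed sign. Against the Cas9 controls Jun fell (-0.39) and Egr1 (-0.03), Twist2 (-0.37) and the Slc6a6 peak (-0.11) changed sign too. The 5 lists did not pass without the low-share samples, with the alveolar type 2 list at adjusted p = 0.611.

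In the Runx2 knockouts of 860T3 the summed accessibility over Runx2 was 452 ± 49.6 CPM in 6 samples (374.9 to 510.1) against 481 ± 8.27 in 2 sgCON samples (475.3 to 487; adjusted p = 0.735). Runx1 (adjusted p = 0.847) and Runx3 (-0.61 ± 0.15, adjusted p = 0.0791) did not pass over all genes, though 1 Runx3 peak (4:135169102-135169401) fell from 64.17 ± 32.72 to 25.6 ± 4.376 (-1.25 ± 0.19, adjusted p = 3e-05). The basement membrane gene Col4a3 rose (0.81 ± 0.17, adjusted p = 0.0457). Adjusted over the list alone, 2 of 18 endothelial genes rose (camera adjusted p = 2.91e-05, lost at 0.0806 with an estimated correlation). Likewise 2 of 16 AP-1 genes fell (camera adjusted p = 0.0101, lost at 0.273). The alveolar type 2 list pointed up (adjusted p = 0.0241, lost at 0.393, past in 2 of 6 alternatives) and the p53 list down (0.0241, lost at 0.273). The knockouts held 1 low-share sample (13.5 percent, sgCON 21.8 to 24.3).

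Of 72690 peaks 1021 changed in the Runx2 knockouts of 860T3, 456 up and 565 down (680 and 469 under loess scaling). Peaks 2.8 kb outside Pyy (11:102110488-102110787; 2.15 ± 0.30, adjusted p = 4.79e-06) and inside Abca4 (3:122130828-122131127; 1.36 ± 0.19, adjusted p = 5.51e-06) rose, and peaks inside Ttll11 (2:35898849-35899148; -2.01 ± 0.27, adjusted p = 3.28e-06) and Lrch1 (14:74831256-74831555; -2.65 ± 0.37, adjusted p = 4.79e-06) fell. The Abca4, Lrch1 and Runx3 peaks did not pass against the 1 Cas9 sample. The count was 455 without Runx2 guide 4 replicate 3, 539 without the merged guide 3 replicates 3 and 5, 624 without guide 4 replicate 5, 3162 without the merged sgCON replicates 2 to 5 and 3851 without sgCON replicate 1. With the column run as a term it was 3525. The Runx2 knockout differed between lines at 0 of 83579 peaks in edgeR, with 15370 at an unadjusted p below 0.05. This test recovered 41.7% of simulated 4-fold changes. It found 0 without the low-share samples and 8112 without 1183T3 sgCON replicate 1. Over peaks tested in both lines the fold changes ran against each other (r = -0.198). Of those called in both 26 rose (6.75 from independent lists), 51 fell (18.8) and 8 went opposite ways. The alveolar type 2 list differed between lines, with low-share samples in both (adjusted p = 0.000714, lost at 0.379 with an estimated correlation).

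In the Runx3 knockouts of 1183T3 the summed accessibility over Runx3 was 42.2 ± 18.5 CPM in 2 samples (29.06 to 55.28) against 37.8 ± 17.1 in 3 sgCON samples (18.66 to 51.52; adjusted p = 0.752), and Runx1 (adjusted p = 0.87) and Runx2 (adjusted p = 0.0535) did not pass. Of 20 alveolar type 2 genes 14 fell, 15 when adjusted over the list alone (camera adjusted p = 0.000175), with Sftpb at -2.10 ± 0.41 (adjusted p = 0.00113). Of 17 hematopoietic genes 11 fell and of 17 endothelial genes 10 fell (adjusted p = 0.00224 for each list), with Fli1 at -2.87 ± 0.64 (adjusted p = 0.00208). Cd74 (-2.12 ± 0.41, adjusted p = 0.00112) and the keratin gene Krt7 (-1.62 ± 0.28, adjusted p = 0.000732) fell. In the epithelial identity list 7 genes fell and 1 rose of 23, 8 and 1 when adjusted over the list alone (adjusted p = 0.0316), and in the cell cycle list 3 of 22 rose (adjusted p = 0.0274), with Pcna at 0.65 ± 0.21 (adjusted p = 0.018). All 5 lists were lost at adjusted p = 0.304 with an estimated correlation. Ier2 (0.66 ± 0.15, adjusted p = 0.00205), Junb (0.70 ± 0.19, adjusted p = 0.00803) and the intermediate filament gene Vim (0.58 ± 0.13, adjusted p = 0.00266) rose.

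Of 72907 peaks 6184 changed in the Runx3 knockouts of 1183T3 (1734 up, 4450 down), and 234 up and 251 down under loess scaling. Without the 2 low-share sgCON samples 463 changed. Without these samples all of the genes named here lost their calls, and Fli1 changed sign (0.01). Against the Cas9 controls Ier2 (-0.42), Junb (-0.35), Krt7 (0.43) and the Cped1 peak (-0.26) changed sign. The alveolar type 2 list stood at adjusted p = 0.93 without the low-share samples, within a range of 7.67e-05 to 0.93 over its 6 alternatives. The peaks inside Lamb1 (12:31292431-31292730; 1.81 ± 0.32, adjusted p = 0.00485) and Cped1 (6:22216411-22216710; 1.80 ± 0.34, adjusted p = 0.00487) rose, and a peak 0.639 kb outside S100a2 (3:90589459-90589758; -1.69 ± 0.31, adjusted p = 0.00487) fell. These 3 kept their calls. A peak inside Gphn (12:78350856-78351155; -2.10 ± 0.36, adjusted p = 0.00485) did not. The count was 4 without the merged sgCON replicates 3, 4 and 5, 284 without sgCON replicate 2, 15714 without sgCON replicate 1, 1432 without Runx3 guide 3 replicate 1 and 15 without its replicate 2. The knockouts of 1183T3 were compared with the same sgCON samples. Runx2 and Runx3 knockouts called 2804 peaks down together where 255 were expected from independent lists (r = 0.742 against 0.588 when simulated without a common effect, covariance 0.551 against 0.0907), and part of this excess may come from the shared controls. Against each other they differed at 3250 peaks.

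In the Runx3 knockouts of 860T3 the summed accessibility over Runx3 was 99.6 ± 3.79 CPM in 2 samples of 2 guides (96.94 to 102.3) against 133 ± 46.7 in 2 sgCON samples (99.74 to 165.8; -0.40 ± 0.18, adjusted p = 0.886). Runx1 and Runx2 did not pass (adjusted p = 0.999 for each), and no fixed list passed. Of 72690 peaks 149 changed, 22 up and 127 down. A peak 2.49 kb outside Ly6c1 (15:75051261-75051560; 1.90 ± 0.36, adjusted p = 0.00717) and 1 inside Kifc3 (8:95146098-95146397; 1.58 ± 0.33, adjusted p = 0.0193) rose, and peaks inside Dhrs3 (4:144908823-144909122; -3.22 ± 0.49, adjusted p = 0.000143) and Stard13 (5:151345863-151346162; -3.34 ± 0.58, adjusted p = 0.00254) fell. The count was 0 without Runx3 guide 3 replicate 2, 1 without guide 4 replicate 2, 36 without the merged sgCON replicates 2 to 5 and 6162 without sgCON replicate 1.

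Activation of Runx2 in 1183T3 left the summed accessibility over Runx2 at 481 ± 50.8 CPM in 3 samples (437.7 to 537.2) against 472 ± 38.8 in 4 Cas9 samples (430.7 to 524.3; adjusted p = 0.887). Activation of Runx3 left Runx3 at 47.4 ± 5.41 in 5 samples (39.83 to 54.45) against 56 ± 18.4 (28.6 to 67.53; adjusted p = 0.532). The summed values of the other Runx genes did not pass in either, save that with the column run as a term Runx3 was higher by 0.84 with Runx2 activation (adjusted p = 0.0479). The keratin gene Krt18 rose by 0.99 ± 0.15 with Runx2 (adjusted p = 3.9e-05) and by 1.04 ± 0.14 with Runx3 (adjusted p = 1.73e-06). The splicing regulator gene Esrp2 rose by 0.56 ± 0.11 (adjusted p = 0.000414) and 0.46 ± 0.09 (adjusted p = 0.000526). In the epithelial identity list 8 of 23 genes rose with Runx2, 10 when adjusted over the list alone (camera adjusted p = 0.000132, range over 6 alternatives 8.48e-09 to 0.0046). With Runx3 13 rose and 1 fell (adjusted p = 0.000354, range 1.49e-06 to 0.00777). The list was lost at adjusted p = 0.0945 and adjusted p = 0.134 with an estimated correlation. It also rose in sgCON against the same Cas9 controls, with 16 of 23 genes up (adjusted p = 0.000115) and no Runx gene activated, so part of the rise may lie in the Cas9 controls.

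The gut and liver endoderm list rose with 4 of 20 genes with Runx2 (adjusted p = 0.0187, lost at adjusted p = 0.289) and 5 with Runx3 (adjusted p = 0.0121, lost at adjusted p = 0.384). Hnf4a rose by 0.92 ± 0.23 (adjusted p = 0.0047) and 0.91 ± 0.21 (adjusted p = 0.00132), and Hnf1b by 0.58 ± 0.14 with Runx2 (adjusted p = 0.00243). Endothelial genes rose too, 5 of 17 with Runx2 (adjusted p = 0.00295, lost at adjusted p = 0.289) and 6 of 17 with Runx3 (adjusted p = 0.0259, lost at adjusted p = 0.384). With Runx2 the alveolar type 2 list, with 3 up and 1 down of 20, pointed up (adjusted p = 0.0347, lost at adjusted p = 0.417) and the cell cycle list, with 4 down of 22, pointed down (adjusted p = 0.0347, lost at adjusted p = 0.295). The gut and liver endoderm, endothelial and alveolar type 2 lists also pointed up in sgCON against these Cas9 controls. The alarmin gene Il33 rose by 0.80 ± 0.16 (adjusted p = 0.000472) and 0.77 ± 0.14 (adjusted p = 0.000106), and the matrix protease gene Mmp9 by 1.13 ± 0.21 (adjusted p = 0.000324) and 1.37 ± 0.19 (adjusted p = 3.14e-06).

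Single mesenchymal, chemokine and TGF-beta feedback genes fell, but their lists did not pass. With Runx2 and with Runx3, adjusted p was 0.286 and 0.191 for the epithelial-mesenchymal transition list, 0.106 and 0.149 for NF-kB and cytokines and 0.06 and 0.0749 for TGF-beta. The epithelial-mesenchymal transition factor gene Snai2 fell by 0.90 ± 0.21 with Runx2 (adjusted p = 0.00236) and by 1.08 ± 0.18 with Runx3 (adjusted p = 4.58e-05). Prrx1 fell by 0.91 ± 0.22 (adjusted p = 0.0039) and 0.92 ± 0.19 (adjusted p = 0.000561). Ccl20 fell by 1.28 ± 0.22 (adjusted p = 0.000161) and 1.36 ± 0.19 (adjusted p = 5.02e-06) and the NF-kB subunit gene Relb by 0.60 ± 0.13 (adjusted p = 0.00105) and 0.61 ± 0.11 (adjusted p = 9.72e-05). The TGF-beta feedback gene Skil fell by 0.68 ± 0.13 (adjusted p = 0.000546) and 0.62 ± 0.11 (adjusted p = 0.000149) and the RUNX corepressor gene Tle4 by 0.57 ± 0.13 (adjusted p = 0.00156) and 0.61 ± 0.11 (adjusted p = 9.64e-05). Against the sgCON controls Ccl20 (0.17 and 0.09), Snai2 (0.88 and 0.70), Prrx1 (0.48 and 0.47) and Hnf4a (-0.80 and -0.81) changed sign, as did Mmp9 with Runx2 (-0.03). Krt18 (0.38) and Hnf1b (0.11) with Runx2 and Mmp9 (0.21) with Runx3 did not pass there.

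Of 72907 peaks 12086 changed with Runx2 (5668 up, 6418 down) and 15970 with Runx3 (7426 up, 8544 down). Scaled by library size alone, 8276 rose and 4535 fell with Runx2 and 10704 rose and 6013 fell with Runx3. A peak inside Accsl (2:93928960-93929259) rose by 2.18 ± 0.27 (adjusted p = 4e-07) and 2.22 ± 0.25 (adjusted p = 5.33e-09). A peak inside Poln (5:34075327-34075626) rose by 2.27 ± 0.28 with Runx2 (adjusted p = 2.04e-07) and a peak 1.89 kb outside Krt18 (15:102033768-102034067) by 1.94 ± 0.23 with Runx3 (adjusted p = 2.91e-08). Peaks inside Psd3 (8:68171514-68171813; -3.65 ± 0.35 and -2.82 ± 0.26), inside Soat2 (15:102150727-102151026; -2.48 ± 0.27 and -2.94 ± 0.23) and 4.87 kb outside Tbc1d31 (15:57906669-57906968; -1.85 ± 0.20 and -1.78 ± 0.17) fell. Against sgCON the Tbc1d31 peak (0.39 and 0.46) and with Runx3 the Psd3 peak (0.18) turned. The Runx2 count was 5409 and 6759 without Runx2 replicates 2 and 3. Without Cas9 replicates 1, 3 with 4, and 5 it was 7711, 6299 and 19104. The Runx3 count was 10294 without Cas9 replicate 1 and 9198 without replicates 3 with 4. Of the Cas9 samples only replicate 5 lay in the column run of the activated ones. With that run as a term 7687 and 8683 peaks changed.

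Largely the same peaks were called in both activation comparisons of 1183T3. In 1183T3 4350 peaks rose in both, where 577 were expected from independent lists and 882 were found with the Cas9 controls split between the comparisons. Likewise 5609 fell in both (752, and 2040 with split controls). The fold changes were related (r = 0.899, against 0.445 simulated and 0.667 with split controls; covariance 0.473, against 0.0396 and 0.426). Runx2 and Runx3 activation differed from each other at 0 of 72907 peaks in edgeR, with 974 at an unadjusted p below 0.05. Of the 9959 peaks changed in the same direction by both, 7022 were also called in that direction in the sgCON controls against the Cas9 controls, and 7 in the other direction. Part of the excess may therefore come from the shared Cas9 controls.

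In 853T2 activation of Runx2 left Runx2 at 401 ± 19.9 CPM in 3 samples (377.8 to 414.2) against 330 ± 15.3 in 2 Cas9 samples (319.3 to 341; adjusted p = 0.558). Of 15 Runx2 peaks tested 1 rose and 1 fell with it. With activation of Runx3, Runx3 stood at 29 ± 5.22 in 3 samples (22.99 to 32.27) against 18.7 ± 19.4 (4.968 to 32.43; adjusted p = 0.697). Without the low-share Cas9 sample Runx3 was higher by 2.57 in both, past the threshold. That sample, at 32.43 CPM, was the only control in the column run of the activated samples, and the remaining 1 stood at 4.968, so this rise cannot be told from a difference between the runs. The extracellular matrix list pointed up, with 3 of 19 genes up with Runx2 (adjusted p = 0.00019) and 1 up with Runx3 (adjusted p = 0.000679) when adjusted over the list alone. It was lost at adjusted p = 0.804 and 0.753 with an estimated correlation. It passed in 4 of 6 alternatives, with adjusted p from 8.4e-08 to 0.703 for Runx2 and from 3.47e-07 to 0.544 for Runx3, and pointed down with the column run as a term. The lowest values were those without the low-share Cas9 sample. The gut and liver endoderm list pointed down, with 2 of 17 genes down (adjusted p = 0.000155) and 3 down (adjusted p = 0.000814) when adjusted over the list alone, lost at adjusted p = 0.0962 and 0.176. It passed in all 6 alternatives, at adjusted p = 0.0105 and 0.0232 without the low-share Cas9 sample.

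Of 42070 peaks tested in 853T2, 3082 changed with Runx2 (2383 up, 699 down) and 2419 with Runx3 (1824 up, 595 down). A peak 0.652 kb outside Smyd4 (11:75406210-75406509) rose from 27.7 ± 2.383 to 112 ± 19.85 with Runx2 (1.96 ± 0.23, adjusted p = 2.77e-06) and by 1.81 ± 0.23 with Runx3 (adjusted p = 1.38e-05). A peak 0.906 kb outside Vim (2:13583583-13583882) rose by 3.77 ± 0.45 with Runx2 (adjusted p = 5.28e-06) and a peak at Wnt7b (15:85574594-85574893) by 2.15 ± 0.29 with Runx3 (adjusted p = 2.46e-05). Peaks at Slc3a1 (17:85052442-85052741; -2.18 ± 0.27 and -2.14 ± 0.27), Lbp (2:158306267-158306566; -2.10 ± 0.26), Onecut1 (9:74866793-74867092; -2.63 ± 0.37) and Mov10 (3:104796467-104796766; -1.87 ± 0.28) fell. These peaks kept their calls without the low-share Cas9 replicate 1, and the counts were then 12030 and 10468. It was the only control in the run of the activated samples, so activation and run could not be separated without it. Without the merged Cas9 replicates 2 to 5 they were 306 and 225, and with the column run as a term 337 and 248. The Runx2 count was 911 without the merged Runx2 replicates 1 and 4. The Runx3 count was 892 without the merged Runx3 replicates 1 and 3, 1429 without its replicate 2 and 1085 without its replicate 4. The 2 activations differed at 0 peaks in edgeR, with 494 at an unadjusted p below 0.05. Part of their 1579 common rises (103 in independent lists; r = 0.904 against 0.545 simulated, covariance 0.415 against 0.0688) may come from the shared controls.

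The activation effects of the 2 lines differed, at 893 of 102422 peaks for Runx2 and 3546 of 104076 for Runx3. The gut and liver endoderm list was lower in 853T2 (adjusted p = 5.43e-07 for Runx2 and 2.19e-07 for Runx3), as was the epithelial identity list (adjusted p = 6.56e-06 and 4.62e-06), and the extracellular matrix list was higher (adjusted p = 0.00253 and 0.00031). The 3 lists were lost with an estimated correlation, at adjusted p = 0.29, 0.29 and 0.872 for Runx2, and for Runx3 at 0.219 for the first 2 lists. Among genes Krt18 (-0.82 ± 0.15, adjusted p = 0.0143), Esrp2 (adjusted p = 0.0143) and Hnf1b (adjusted p = 0.0114) had lower effects of Runx3 activation in 853T2 than in 1183T3, and Prrx1 (adjusted p = 0.0125) and Ccl20 (adjusted p = 0.0346) differed in the other direction. The differences of Mmp9 (-0.88, adjusted p = 0.145) and Snai2 (0.78, adjusted p = 0.172) did not pass with Runx3. With Runx2 those of Krt18 (-0.57, adjusted p = 0.238) and Esrp2 (-0.72, adjusted p = 0.0755) did not pass, though that of Esrp2 was as large as with Runx3 (-0.69). Leaving out any of the 12 samples of the Runx2 test moved its count by more than 1.5-fold. It was 524, 442 and 60 without 853T2 Runx2 replicates 2, 3 and 1 with 4. Without 1183T3 Runx2 replicates 1, 2 and 3 it was 215, 531 and 248. Without 1183T3 Cas9 replicates 1, 2, 5 and 3 with 4 it was 481, 586, 6277 and 432. Without 853T2 Cas9 replicate 1 and the merged replicates 2 to 5 it was 4422 and 2625. For Runx3 it was 2294, 1840 and 1191 without 853T2 Runx3 replicates 2, 4 and 1 with 3. It was 2249 without 1183T3 Runx3 guide 2 replicate 1. It was 2152 and 9949 without 1183T3 Cas9 replicates 1 and 5, and 9437 without 853T2 Cas9 replicate 1.

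The 2 kinds of control differed. In 1183T3 29026 of 72907 peaks (39.8 percent) changed between sgCON and Cas9, 16706 up and 12320 down, and 15719 without the 2 low-share sgCON samples. With DESeq2 size factors 20712 rose and 6904 fell. In the epithelial identity list 16 of 23 genes rose and 1 fell (camera adjusted p = 0.000115, lost at adjusted p = 0.0682 with an estimated correlation). In the alveolar type 2 list 16 of 20 rose (adjusted p = 0.000508, lost at adjusted p = 0.242). In the epithelial-mesenchymal transition list 11 of 22 fell and 3 rose (adjusted p = 0.0151, lost at adjusted p = 0.217). The endothelial list (12 of 17 up, adjusted p = 0.00184, lost at 0.217), the gut and liver endoderm list (10 up and 2 down of 20, adjusted p = 0.00853, lost at 0.217) and the hematopoietic list (10 up and 1 down of 17, adjusted p = 0.0165, lost at 0.421) pointed up. The AP-1 list (5 down and 1 up of 16, adjusted p = 0.0228, lost at 0.217) pointed down. Without the 2 low-share sgCON samples the alveolar type 2, endothelial, hematopoietic and AP-1 lists did not pass, at adjusted p = 0.848, 0.669, 0.669 and 0.258. Peaks inside Cdhr2 (13:54703870-54704169; 2.83 ± 0.32) and Zfpm1 (8:122298517-122298816; 3.60 ± 0.43) rose and the Tbc1d31 (-2.24 ± 0.22) and Psd3 (-3.00 ± 0.34) peaks fell. In 860T3, with 1 Cas9 sample, 6318 of 72690 peaks changed, 3958 up and 2360 down, and 5103 up and 1651 down when scaled by library size alone. Without sgCON replicate 1 the count was 12660. Peaks at Glis1 (4:107496121-107496420; 3.79 ± 0.42) and Tmco4 (4:139007915-139008214; 3.80 ± 0.44) rose and at Lrrc8a (2:30258572-30258871; -2.65 ± 0.29) and Psd3 (8:68191774-68192073; -3.17 ± 0.35) fell. In 860T3 4 lists passed, each pointing up, and all were lost with an estimated correlation. They were extracellular matrix (4 of 22 genes up, adjusted p = 0.0146, lost at 0.221), epithelial identity (2 of 23, 0.0215, lost at 0.0863), gut and liver endoderm (3 of 18, 0.0215, lost at 0.0863) and endothelial genes (3 of 18, 0.024, lost at 0.221).

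In the Cas9 controls of 853T2 against those of 1183T3 (2 and 4 samples) Krt18 was higher by 1.37 ± 0.16 (adjusted p = 0.0023) and Krt8 by 1.21 ± 0.17 (adjusted p = 0.00438). The tight junction gene Cldn3 was higher by 1.89 ± 0.22 (adjusted p = 0.00246) and the endoderm factor gene Hnf1a by 1.93 ± 0.25 (adjusted p = 0.00353). The mesenchymal genes Prrx1 (-2.24 ± 0.23, adjusted p = 0.0017), Cdh2 (-3.56 ± 0.42, adjusted p = 0.00269), Twist1 (-5.23 ± 0.69, adjusted p = 0.00369) and Col6a3 (-1.74 ± 0.19, adjusted p = 0.00225) were lower, as were Sox2 (-3.95 ± 0.66, adjusted p = 0.00731) and Runx2 (-0.55 ± 0.11, adjusted p = 0.0162). Of 23 epithelial identity genes 10 were higher, 15 when adjusted over the list alone (adjusted p = 2.39e-08, lost at adjusted p = 0.413 with an estimated correlation). Of 23 mesenchymal genes 9 were lower (adjusted p = 1.89e-08, lost at adjusted p = 0.413). In this comparison 25569 of 126904 peaks differed, 30144 without the low-share sample and 11199 without the merged 853T2 Cas9 replicates 2 to 5.

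Against the 1 Cas9 sample of 860T3, 853T2 differed at 22376 peaks, 7957 higher and 14419 lower, and 10347 higher and 10519 lower when scaled by library size alone. Without the low-share sample 26754 differed. Cldn3 (1.92 ± 0.34) and Esrp2 (1.12 ± 0.20) were higher. Bmp2 (-3.21 ± 0.34), the TAZ gene Wwtr1 (113.3 against 260 CPM), Prrx1 (-2.32 ± 0.27), Cdh2 (-3.72 ± 0.48) and Twist1 (-5.27 ± 0.76) were lower. As 860T3 had 1 Cas9 sample, the calls here and against 1183T3 took its spread from the other groups. The lines 1183T3 and 860T3 were closer, with 4228 peaks, 1862 higher and 2366 lower, and 2262 higher and 1586 lower when scaled by library size alone. Bmp2 (-2.60 ± 0.27, adjusted p = 0.00932) and the YAP targets Ccn1 (-1.10 ± 0.16, adjusted p = 0.0266) and Ccn2 (-1.09 ± 0.20, adjusted p = 0.0438) were lower in 1183T3 and Fbln2 was higher (1.63 ± 0.26, adjusted p = 0.0288). This count was 2147 without 1183T3 Cas9 replicate 2, 2641 without replicate 1, 2292 without the merged replicates 3 and 4 and 8990 without replicate 5.

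The Cdkn2a and Cdkn2b segment held almost no reads in 860T3. CPM in this paragraph are relative to the unscaled totals of the libraries of each line. Between 4:89277652 and 4:89575864 93 peaks held 3 reads in the 30 libraries of 860T3 (0.0651 CPM), against 24891 in 1183T3 (346 CPM) and 7145 in 853T2 (381 CPM). In the Cas9 controls the cell-cycle inhibitor gene Cdkn2b held 0 reads in 860T3, at least 91.3-fold lower than in 1183T3 and at least 120-fold lower than in 853T2. Cdkn2a, which reaches beyond the segment, held 9 reads there, with ratios of 19 (9.89 to 41.9) and 35.6 (18.5 to 78.6). A peak inside Trp53 (11:69585874-69586173) held 0 reads in all 81 libraries, and its neighbour at 11:69581328-69581627 held 20.7, 19.8 and 18.6 CPM in 1183T3, 853T2 and 860T3.

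**Figure D5:**
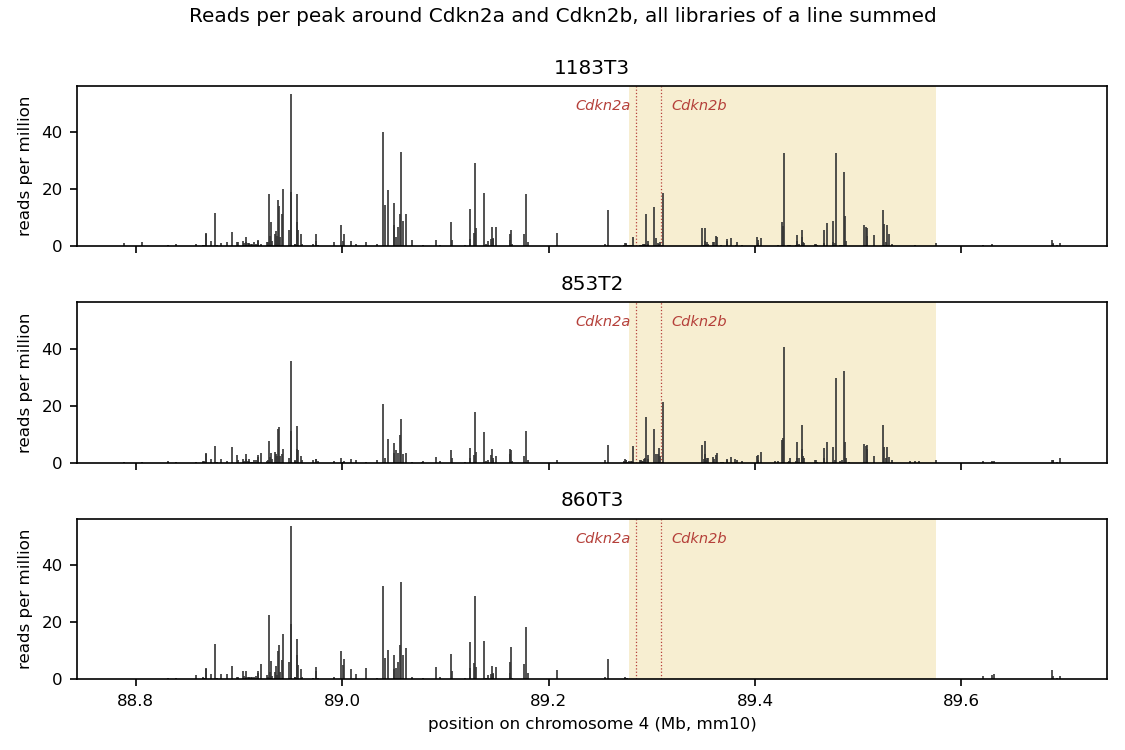
CPM, relative to unscaled library totals, of each peak around Cdkn2a and Cdkn2b by position on chromosome 4 in megabases, with the libraries of each line summed and the segment shaded. Peaks of 860T3 hold almost no reads across the segment while the other lines keep theirs.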

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

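Of the tests in this part, those on the cloned Neat1 DNA, the loss of RUNX, the column run and the activation of either gene in 853T2 were chosen after the result was seen, and the others before.

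The search for single samples far from the others covered 30 tests, with several measures over the same groups, and picked out 3, where chance picks out about 1 in 20, or 1.5 here. Neat1 stood at 357.5 CPM in the Cas9 control replicate 5 of 1183T3, and the nearest other sample of that group at 231.9. Runx3 stood at 28.6 in the same sample, and the nearest other at 61.7. This sample was the only one of its group in its column run, so both values may reflect the run. Runx3 stood at 176.6 in the Runx1 knockout of 860T3 with guide 5, replicate 1, and the nearest other at 141.8.

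Effects of the same perturbation that differed between lines were picked out by the test of the difference. The Runx1 knockout differed between 1183T3 and 860T3 at 7739 peaks. Runx2 activation, by different guides, differed between 853T2 and 1183T3 at 893 peaks, and Runx3 activation at 3546.

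The opening of Neat1 and of immediate early genes in the Runx1 knockouts was weighed first. A clone of Neat1 alone would leave the surroundings unchanged, but peaks within 10 kb outside rose in both lines (smaller median 2.03). A longer clone remains open. A transcribed state varying between knockout samples would make Neat1 and the AP-1 list rise together in both lines. Across 8 samples each, r was 0.781 in 1183T3 (exact p = 0.0246, rho 0.762 with exact p = 0.0368, and r = 0.0174 without the 2 samples furthest out in Neat1). It was -0.745 in 860T3 (exact p = 0.0362, rho -0.714 with exact p = 0.0576, and r = -0.769 without 2). No such state was found in both lines (adjusted p = 0.0491, 0.0491, 0.0491 and 0.0576 over 4 relations). A state that all samples share was not tested. Preparation remains open, since the column run of these libraries held only Runx1 knockouts.

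The lower signal at alveolar type 2, hematopoietic and endothelial genes in the knockouts of 1183T3 was weighed next. An uneven background of the sgCON samples was predicted to lower any set of genes with a like signal. In 9 of 9 combinations of list and knockout the median lay below the 2.5th percentile of matched random lists. These were matched on mean signal over all samples of the line, sgCON included, and not on the number or strength of peaks. They therefore cannot exclude such a background. A loss of RUNX would lower these lists against the Cas9 controls too, but 6 of 9 medians lay above 0 there, for example 0.414 for alveolar type 2 genes in the Runx1 knockout, where the value against sgCON was -1.21. The values against the Cas9 controls argue against a loss of RUNX as the sole cause, but the uneven background was not excluded. Without the 2 low-share sgCON samples the alveolar type 2 list stood at adjusted p = 0.586 in the Runx1 knockout, so a property of those 2 samples, such as a trace of other cells or cell states, may account for it and was not tested. They were also the only sgCON samples of 1183T3 in their column run.

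The changes common to Runx2 and Runx3 activation in 1183T3 were weighed last. If the Cas9 controls stood apart, sgCON against the Cas9 samples not used for the call would move the same way. It did at 96.1 and 92.5 percent of peaks for the 2 divisions, 93.3 percent together. It was called so at 2082 of 2902 and 3580 of 9687 peaks. Both divisions held Cas9 samples of 1 run, so the run stays open. With it as a term 41.5 percent stayed called the same way in both. In both activations of 853T2 64.7 percent had the same sign, which leaves activation of either gene open. The Cas9 controls may hold part of the common change.

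The samples of each comparison were also divided in other ways, on up to 20000 peaks and with the compared groups alone. The Runx1 knockout of 1183T3 changed 3743 peaks and the highest other of 100 divisions 31, so 1 of 100 reached the real count. That division also follows the column run, which could not be excluded. The Runx3 activation of 1183T3 changed 6181, the highest other 5016, and 1 of 100 reached the real count. Both largely follow the column run, which was not excluded. The Runx2 knockout of 1183T3 changed 0, which every division reaches (100 of 100), so this tested nothing and chance could not be excluded. The division with the highest count, 1763, had sgCON replicate 1 among the knockouts. For Runx2 activation in 1183T3 2 of 35 divisions reached the real count of 3809. Cas9 replicates 1, 2 and 3 with 4 against the rest, which follows the column run, changed 5893. With the run as a term 7687 peaks changed in the fit over all peaks, but chance could not be excluded. For sgCON against Cas9 in 1183T3, 2 of 35 reached the real count of 3066, and the same set of Cas9 samples against the rest changed 3572, so chance could not be excluded there either.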

How the results depend on the processing

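The tests without the low-share samples, with the column run as a term, with other merging of replicates, with local copy-number offsets and without samples under 500000 counts were chosen after the results were seen. The direction of single genes and peaks held more often than the counts of changed peaks. Of 290 counts under another setting, leaving out single samples aside, 145 stayed within 1.5 times the reported count and 145 did not. Where a count moved, the cause was not tested, save where fewer samples or a stricter threshold explain it by construction. Library size alone moved no count by more than 1.5 times, nor did local copy-number offsets or a separate group for each guide. With 8 or fewer samples a side and 11 libraries under 500000 counts, 2-fold changes were mostly missed. In the Runx1 knockout of 1183T3 28.6 percent of simulated ones were found. Motif accessibility was not run. The 1 Cas9 sample of 860T3 could not be left out, and a column-run term could not be fitted for the Runx1 knockouts. Of 300 list tests 61 passed, and between 49 and 68 did under the other settings, with 41 kept without the low-share samples and 9 lost, 22 gained and 12 turned. With peaks within 1 kb of a gene end 41 were kept, 19 lost and 3 turned.

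The numbers of the replicates were not shown to pair the samples. Of 74 pairs in 15 comparisons 15 had a correlation over 0.1, with a range of -0.326 to 0.504, and in 0 comparisons with 3 or more pairs did every pair. The Runx3 knockout of 1183T3 had 2 pairs, at 0.2 and 0.504, too few to set a pairing by the rule used. With the replicate number as a block the Runx1, Runx2 and Runx3 knockouts of 1183T3 changed 3463, 2 and 105 peaks, the Runx2 and Runx3 knockouts of 860T3 269 and 8982, Runx2 and Runx3 activation 25844 and 29489 in 1183T3 and 869 and 426 in 853T2, and sgCON against Cas9 in 1183T3 17971. The Runx2 knockout then differed between lines at 3 peaks and Runx2 activation at 2749. No paired analysis was possible for the comparisons with the Cas9 sample of 860T3 because the groups share fewer than 2 numbers after merging.

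Leaving out single samples moved 60 of 160 counts by more than 1.5 times. The count ran from 9228 to 20555, 0 to 16508 and 4 to 15714 for the Runx1, Runx2 and Runx3 knockouts of 1183T3, and from 7092 to 12926, 455 to 3851 and 0 to 6162 for those of 860T3. For activation of Runx2 and Runx3 it ran from 5409 to 19104 and 9198 to 22503 in 1183T3, and from 306 to 12030 and 225 to 10468 in 853T2. For sgCON against Cas9 the range was 20199 to 33757 in 1183T3 and 6658 to 12660 in 860T3. Between lines it was 2147 to 8990 for 1183T3 against 860T3, 11199 to 35055 for 853T2 against 1183T3 and 16679 to 26754 for 853T2 against 860T3. Differences of effects ran from 5819 to 8369 for the Runx1 knockout, 0 to 8112 for the Runx2 knockout, 60 to 6277 for Runx2 activation and 1191 to 9949 for Runx3 activation. Where a lone sample remained in a group, it was assumed to vary like the other groups.

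For the knockouts of 1183T3, in the order Runx1, Runx2 and Runx3, the counts were 10089, 557 and 485 with loess offsets, 35777, 17114 and 23583 with the stricter filter, and 76067, 35908 and 34170 without a filter. They were 3743, 0 and 1059 with only the groups compared, 25302, 25635 and 9503 against the other control, 9271, 0 and 0 with wider merging and 6838, 22 and 463 without the low-share samples. With both controls together the Runx2 and Runx3 knockouts changed 10635 and 181 peaks, and without samples under 500000 counts 13379 and 15067. With counts summed per guide the Runx2 knockout changed 3259, and with every library its own sample the Runx3 knockout 3493. Guides 2, 3, 4 and 5 against Runx1 alone changed 2458, 1225, 1994 and 3308 peaks, and guides 3 and 4 against Runx2 1405 and 1342.

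For the knockouts of 860T3, in the same order, the counts were 5620, 626 and 22 with the stricter filter, 17591, 12613 and 2859 against the other control, and 15747, 4276 and 2631 with every library its own sample. The Runx2 and Runx3 knockouts changed 160 and 0 peaks with only the groups compared, 477 and 14 with wider merging and 3525 and 68 with the column run as a term. With counts summed per guide the Runx1 and Runx2 knockouts changed 4127 and 464, and with an absolute log2 fold change of at least 1 the Runx1 knockout 3754. The Runx3 knockout changed 57 peaks without a filter, 0 with both controls together and 9 with the DESeq2 Wald test. Guides 1 to 5 against Runx1 alone changed 1991, 1629, 166, 594 and 2175 peaks, guides 3 and 4 against Runx2 49 and 480, and guides 3 and 4 against Runx3 1 and 0.

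For activation in 1183T3, Runx2 first, the counts were 5316 and 8509 without a filter, 1482 and 3783 with both controls together, 2155 and 3503 with wider merging, 7687 and 8683 with the column run as a term and 6962 and 7614 with an absolute log2 fold change of at least 1. Against the other control Runx2 changed 5308. With counts summed per guide Runx3 changed 7921 and with guide 1 alone 4780. For activation in 853T2 they were 111 and 67 with the stricter filter, 46 and 48 without a filter, 1660 and 1296 with only the groups compared, 253 and 2 with wider merging and 12030 and 10468 without the low-share sample. They were 10295 and 8178 with every library its own sample, 337 and 248 with the column run as a term and 638 and 428 with the DESeq2 Wald test.

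For sgCON against Cas9 in 1183T3 the counts were 17939 with loess offsets, 58377 with the stricter filter, 80385 without a filter, 10724 with only the groups compared, 12914 with wider merging, 15719 without the low-share samples and 45267 without samples under 500000 counts. In 860T3 they were 1892 without a filter, 2174 with only the groups compared, 17644 with every library its own sample and 14315 with the column run as a term. For 1183T3 against 860T3 they were 1211 without a filter, 6605 with only the groups compared, 656 with wider merging, 7018 without the low-share samples, 14878 with every library its own sample, 11199 with the column run as a term and 701 with the DESeq2 Wald test. For 853T2 against 1183T3 and against 860T3 they were 15224 and 12415 without a filter, 10704 and 12939 with wider merging and 13765 and 9545 with the DESeq2 Wald test, and against 860T3 12839 with only the groups compared and 34053 with the column run as a term.

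Differences of effects, in the order Runx2 activation and Runx3 activation, were 2 and 863 without a filter, 0 and 0 with wider merging, 4422 and 9437 without the low-share samples, 7713 and 10192 with every library its own sample and 5757 and 10308 with the column run as a term. With DESeq2 size factors Runx2 activation differed at 1504. Without a filter the Runx1 knockout differed at 3896 and the Runx2 knockout at 4, and the Runx2 knockout at 382 with every library its own sample and 2 with the column run as a term.

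Some genes changed direction, and the cause was not tested. Runx1 in its knockout of 1183T3 was -0.21 with loess offsets, past the threshold (adjusted p = 0.0272). Against the Cas9 controls, Egr1 (-0.034), Ikzf1 (0.049), Jun (-0.39), Lpcat1 (0.035), Runx2 (-0.013), Sftpb (0.51), Twist2 (-0.37) and the Slc6a6 peak (-0.11) turned in the Runx2 knockout of 1183T3. So did Ier2 (-0.42), Junb (-0.35), Krt7 (0.43), Sftpb (0.048) and the Cped1 peak (-0.26) in the Runx3 knockout of 1183T3, and Ccl20 (-0.49) and Ptgs2 (-0.14) in the Runx1 knockout of 860T3. With both controls together Jun was -0.083 in the Runx2 and Ier2 -0.049 in the Runx3 knockout of 1183T3. Without the low-share samples Ikzf1 was 0.33, Lpcat1 0.29 and Sftpb 0.35 in the Runx2 knockout and Fli1 0.011 in the Runx3 knockout. Activation in 1183T3 set against sgCON turned Ccl20 (0.17 with Runx2 and 0.093 with Runx3), Hnf4a (-0.80 and -0.81), Prrx1 (0.48 and 0.47), Snai2 (0.88 and 0.70) and the Tbc1d31 peak (0.39 and 0.46), with Mmp9 (-0.031) for Runx2 and the Psd3 peak (0.18) for Runx3. With both controls together Hnf4a was -0.065 with Runx2 and -0.069 with Runx3, and Runx3 was 0.84 in Runx2 activation with the column run as a term (adjusted p = 0.0479).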

Other observations

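The values of this part were chosen after the results were seen. Neat1 was also higher in the activated samples of 1183T3 than in the Cas9 controls, by 1.00 ± 0.27 with Runx2 (adjusted p = 0.00837) and by 0.98 ± 0.25 with Runx3 (adjusted p = 0.00351), and Malat1 by 0.98 (adjusted p = 5.42e-05) and 0.96 (adjusted p = 7.28e-06). Neat1 reached 527 ± 44.2 CPM in 3 samples and 518 ± 26.4 in 5, against 263 ± 63 in 4 Cas9 samples, far below the 9190 ± 3870 of the Runx1 knockouts of that line. In the controls of 1183T3 Neat1 differed between column runs. The 1 Cas9 sample in the run of the activated samples stood at 357.5 and the other 3 at 231.1 to 231.9, and for sgCON these were 485.5 and 255.3 to 275.8, but the 2 Runx3 knockout samples in that run stood at 319.1 and 240.5. Whether the rise lies with the run was left open. In 853T2 Neat1 did not pass with Runx2 (-0.11 ± 0.26, adjusted p = 0.957) or Runx3 (-0.12 ± 0.26, adjusted p = 0.932), and Malat1 did not either (adjusted p = 0.777 and 0.839). Malat1 differed between the lines with Runx3 (-1.15, adjusted p = 0.00724). Outside the gene, the rise of the Runx1 knockouts reached further on the lower side of Neat1 on chromosome 19, with medians of 2.21 in 1183T3 and 3.45 in 860T3 within 10 kb, than on the upper side, with 1.08 and 0.727.

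Within Runx1 itself a peak at 16:92609367-92609666 rose in the Runx1 knockouts of both lines, by 0.75 ± 0.20 in 1183T3 (adjusted p = 0.00427) and 0.73 ± 0.14 in 860T3 (adjusted p = 0.000178). The nearby peak at 16:92608131-92608430 fell in 1183T3 (-0.92 ± 0.33, adjusted p = 0.0369) and rose in 860T3 (0.83 ± 0.22, adjusted p = 0.00514).

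Knockouts of different genes were also set directly against each other, without a control. Runx1 and Runx2 knockouts differed at 14223 of 72907 peaks in 1183T3 and at 6506 of 72690 in 860T3, and Runx2 and Runx3 knockouts at 575 in 860T3. Against the shared sgCON samples, Runx1 and Runx2 knockouts of 1183T3 both called 2812 peaks down (592 from independent lists) and 463 up (88.6), with 52 in opposite directions, r = 0.55 against 0.585 simulated and a covariance of 0.487 against 0.0912. Runx1 and Runx3 knockouts both called 2719 down (629) and 422 up (146), with r = 0.475 against 0.55 and a covariance of 0.465 against 0.0916. In 860T3 Runx1 and Runx2 knockouts both called 326 up (24.8) and 273 down (42), with r = 0.416 against 0.59 and a covariance of 0.174 against 0.0666. The other pairs there had no excess covariance, with 0.0631 against 0.0647 for Runx1 and Runx3 and -0.0223 against 0.0641 for Runx2 and Runx3. Part of these excesses may come from shared controls, and the 1183T3 Runx2 knockout fell to 22 peaks without the 2 low-share sgCON samples.

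Between lines, activation called 389 peaks up in both lines for Runx2 (177 from independent lists), 63 down (86.6) and 88 in opposite directions, with r = 0.225. For Runx3 these were 354 up (189), 65 down (90.3) and 160 opposite, with r = 0.172. Whole chromosomes differed between the lines. The median log2 fold change of chromosome 4 lay -0.9 from that of all peaks in 853T2 against 860T3, chromosome X lay -0.785 from it in that comparison and -0.855 in 1183T3 against 860T3, and chromosome 13 lay -0.584 from it in 853T2 against 1183T3. Inside Inpp4b a peak at 8:81384113-81384412 held 0 reads in 1183T3, where 119 were expected from the other lines.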
